A study of Mus musculus with 9 samples.

How the data were processed

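RNA from BV2 cells was sequenced in 9 libraries, 3 per group. Per the labels' protocols, cells were grown in DMEM with 10% fetal bovine serum in 5% CO2 at 37 °C, hypoxia was set at 1% oxygen in a hypoxic workstation, and 100 µM ethanolamine was added under hypoxia. RNA was extracted with Qiagen RNeasy columns, and 1.3 µg of total RNA per library went into a SMARTER mRNA sequencing kit, per the labels' protocols. Groups were taken from the sample titles. The treatment tag of the controls names adipocyte differentiation, which goes against their title and the series design, and was not used.

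The authors deposited FPKM per gene and library (fragments scaled by gene length and by the mapped total of the library), with 55335 mouse gene identifiers and symbols. The genome build was GRCm38 (mm10), per the submitters' processing notes; the aligner, the quantifier and their settings are not given in the sources used here. A second deposited table, which bins the same FPKM values, was not used. FPKM divides by the total of each library, so a transcript class that takes more of the total lowers all others, and it depends on the gene length used. Whole reads could not be recovered and the absolute depth is unknown. Between pairs of libraries 0.777% to 1.41% of values under 0.3 FPKM shared a modal ratio, compared on log2 ratios rounded to 2 decimals, which gave relative depths whose largest departure from an additive fit was 0.00778 log2. No 2 library columns were identical. Positions, biotypes and overlaps came from GENCODE mouse release M21 on the same build, which held 55154 of the 55335 identifiers.

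Genes with a mean of at least 1 FPKM over the 9 libraries (11802 of the 27339 above 0 in at least 1 library) were tested on log2(FPKM + 0.5) with limma-trend in limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table; figures in Python 3.11.15 with matplotlib 3.10.9). Means of the 3 groups were fitted over all 9 libraries without covariates, contrasts were tested with moderated statistics, two-sided, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Gene lists (32, of which 26 had at least 5 tested members) were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 26 lists; 32 of 977 listed genes are in more than 1 list. The groups, tests, gene lists, rule for named genes and most alternative settings were fixed before the data were examined. For hypoxia against control and for ethanolamine against hypoxia, the rule named the 6 highest and 6 lowest log2 changes past the threshold with a mean of at least 5 FPKM and a symbol that is not a predicted gene. It also named up to 4 members per described list, or the 2 most abundant where none passed, a fixed set of 16 genes, and the 6 opposite-sign and 4 same-sign genes with the largest smaller change in both comparisons. Members named because a list had 5 or fewer, or because a list's lower members are spelled out, were chosen after their values were seen. Some genes that this rule names are not reported here.

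Noise in simulated data of 11802 genes was drawn independently per gene, with the same spread in all comparisons. The code was tested on these data, in which 67, 67 and 66 genes were changed by 0.5, 1 and 2 on the log2 scale. For hypoxia against control it recovered 40.3%, 95.5% and 97.0% of them, with 3.12% of calls false. For ethanolamine against hypoxia it recovered 59.7%, 94.0% and 100% with 6.11% false, and for ethanolamine against control 52.2%, 92.5% and 95.5% with 5.88% false. A list of 42 genes shifted by 0.5 was called in each comparison, and 1 further, unchanged list was called for ethanolamine against hypoxia and 0 for the others. Alternatives were pseudocounts of 0.1 and 1, no filter and a filter of 5 FPKM, median-of-ratios and quantile scaling, the replicate number as a block, only the groups compared, no mean-variance trend, an estimated correlation, a log2 change of at least 1, and each library left out. A rescaling without ribosomal RNA-like and mitochondrial transcripts and the removal of a trend on length and GC were added after seeing the data. With median-of-ratios scaling the higher share of called genes was 47.0% instead of 41.6% for hypoxia against control and 49.3% instead of 41.1% for ethanolamine against control. Shared libraries were simulated in 100 data sets built from group means and residuals shuffled without replacement; a first version drew residuals with replacement, could repeat a library within a group, and was replaced after its result was seen.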

Results

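Gene expression was measured by RNA sequencing in BV2 cells, an immortalised mouse microglial line. The 9 libraries fell into 3 groups of 3. Control cells were labelled 0 h, hypoxic cells were kept for 24 h at 1% oxygen, and a further group was kept for 24 h in 1% oxygen with 100 µM ethanolamine, a precursor of membrane phospholipids. The series concerns ethanolamine in diabetic retinopathy, and its design sets hypoxia with and without the supplement against control. Values were FPKM, and the number of reads per library is unknown. The low values gave a relative depth that differed 1.32-fold between the deepest and the shallowest library. Library sums of FPKM were 324120 to 370320, and 11556 to 11924 genes reached 1 FPKM. Across the 11802 tested genes, log2(FPKM + 0.5) correlated at 0.974 to 0.983 within groups, at 0.972 to 0.983 between hypoxia and supplemented libraries, and at 0.878 to 0.905 between control and hypoxic libraries. On the second principal component (6.21% of the variance), supplemented library 1 (3.72) lay apart from supplemented libraries 2 and 3 (-17.8 and -21.1) and near the hypoxia libraries (5.65, 15.4 and 12.1). Levels below are FPKM means ± SD of n = 3 libraries per group, and log2 changes are on the log2(FPKM + 0.5) scale, which understates the change of genes with low values. Nothing in the labels says that the libraries came from separate cultures, so p-values measure the spread between these samples only, which may be technical.

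The comparison of hypoxia with control asked how low oxygen changes these cells. Bnip3, a mitophagy receptor induced by hypoxia, rose from 7.54 ± 0.867 FPKM in control to 298 ± 7.15 in hypoxia (SD, n = 3; log2 change 5.22, SE 0.09, limma adjusted p = 4.47e-09). The glucose transporter gene Slc2a1 rose from 32.9 ± 4.36 to 237 ± 16.3 FPKM (log2 change 2.83, SE 0.09, limma adjusted p = 4.89e-08). Nos2, which encodes inducible nitric oxide synthase, rose from 22.8 ± 1.41 to 384 ± 14.2 FPKM (log2 change 4.05, SE 0.07, limma adjusted p = 4.05e-09). Cdc20, an activator of the anaphase-promoting complex, fell from 127 ± 10.7 to 16.4 ± 2.81 FPKM (log2 change -2.92, SE 0.13, limma adjusted p = 2.2e-07). In all, 7011 of 11802 genes passed an adjusted p of 0.05 in limma, 2919 higher and 4092 lower, and 1808 of them had an absolute log2 change of at least 1 (852 higher and 956 lower). High changes among named genes with a mean of at least 5 FPKM were those of the macrophage elastase gene Mmp12 (6.05), Selenbp1 (5.69), Bnip3 (5.22), the coagulation factor gene F10 (4.27) and the HIF prolyl hydroxylase gene Egln3 (4.25). The lowest belonged to Cdc20 (-2.92), Aunip (-2.83), Nek2 (-2.68), the mitotic kinase gene Plk1 (-2.67), Calr3 (-2.60) and the cell cycle transcription factor gene Mybl2 (-2.60). Control and hypoxia differ in labelled time (0 h and 24 h) as well as in oxygen, so this comparison does not separate them.

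Known targets of the hypoxia-inducible factors rose together. Of 44 measured targets outside glycolysis, 36 rose and 4 fell (median log2 change 1.71, camera adjusted p = 5.76e-16), with the same counts when adjusted over the list alone. Besides Bnip3 and Egln3, the glycogen regulator gene Ppp1r3b rose by 3.92, the pyruvate dehydrogenase kinase gene Pdk1 by 1.93 and Vegfa by 1.34 on the log2 scale, Vegfa from 13.5 ± 0.319 to 34.97 ± 1.90 FPKM. The members that fell were Car12, Stc2, Tfrc and Cxcr4. The transcript of Hif1a itself was 42.6 ± 3.28 FPKM in control and 40.4 ± 2.35 in hypoxia (log2 change -0.07, SE 0.07, limma adjusted p = 0.377). Epas1 was 3.09 ± 0.331 and 3.24 ± 0.870 FPKM (limma adjusted p = 0.869). Car9, often used as a hypoxia marker, stayed below the filter, with at most 0.488 FPKM in any of the 9 libraries. All 17 measured glycolysis genes rose (median log2 change 1.07, camera adjusted p = 2.2e-09; adjusted p = 0.156 with an estimated correlation), among them Aldoc (2.00), Pgk1 (1.87), Pfkl (1.84), Pfkp (1.69) and Ldha (0.96). Of 23 tricarboxylic acid cycle genes, 19 fell and none rose in limma (median log2 change -0.45, camera adjusted p = 0.000167; adjusted p = 0.246 with an estimated correlation), with Idh2 at -1.05, Ogdh at -0.94, Suclg2 at -0.72 and citrate synthase (Cs) at -0.65. Autophagy genes rose as a list, 19 of 33 members and none lower (median log2 change 0.33, camera adjusted p = 5.67e-06), including Wipi1 (1.66), Map1lc3a (1.10), Rb1cc1 (0.89) and Atg9a (0.79).

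Inflammatory transcripts rose in hypoxia while interferon-stimulated transcripts fell. Of 31 measured pro-inflammatory genes, 20 rose and 6 fell, with the same counts when adjusted over the list alone (median log2 change 0.63, camera adjusted p = 5.43e-05). Cxcl2, a neutrophil chemoattractant, rose from 4.60 ± 0.527 to 93.2 ± 18.5 FPKM, Il1b from 2.15 ± 0.139 to 29.8 ± 5.90, and the prostaglandin synthase gene Ptgs2 from 14.4 ± 0.733 to 136 ± 18.6. The smaller changes of Il6 (0.69, limma adjusted p = 0.0158) and Tnf (0.31, limma adjusted p = 0.0107) also passed the threshold. The members that fell were Cxcl10, an interferon-induced chemokine, with Casp1, Cd86, Tlr2, Sod2 and Saa3. Of 28 interferon-stimulated genes, 17 fell and 4 rose, or 19 and 4 adjusted over the list alone (median log2 change -0.61, camera adjusted p = 0.0199; adjusted p = 0.516 with an estimated correlation). Rsad2 fell by 2.18, Usp18 by 2.08 and Gbp3 by 1.92 on the log2 scale, and the members that rose were Isg20, Ifi204, Ifi203 and Slfn2. Of 19 angiogenic and growth factor genes, 14 rose, including Mmp12, Csf3 (3.15), the placental growth factor gene Pgf (3.00) and Apln (2.52), and Vegfb and Csf1 fell, or 14 and 3 adjusted over the list alone (median log2 change 1.34, camera adjusted p = 1.1e-05). Alternative activation genes (9 of 12 higher, Klf4 lower; median log2 change 0.85, camera adjusted p = 0.000207) included Il1rn (1.91), Socs3 (1.52) and Clec7a (1.40). Arg1 was listed at 0 in all 3 controls, averaged 1.48 FPKM in hypoxia and was below the test's filter.

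Immediate early genes rose in 16 of 21 cases (median log2 change 0.85, camera adjusted p = 2.19e-05; adjusted p = 0.111 with an estimated correlation), including Cyr61 (2.49), Ier3 (1.87), Dusp6 (1.82) and Dusp1 (1.80), while Fosl1, Ier2, Ier5 and Dusp2 fell. Among homeostatic microglial genes 7 of 14 rose and the cathepsin gene Ctss fell, or 7 and 2 adjusted over the list alone (median log2 change 0.58, camera adjusted p = 0.00598; adjusted p = 0.0659 with an estimated correlation). The colony-stimulating factor receptor gene Csf1r rose from 17.98 ± 1.14 to 69.9 ± 2.49 FPKM, Mertk from 0.192 ± 0.0566 to 3.35 ± 0.148, and Cx3cr1 from 0.195 ± 0.0553 to 2.47 ± 0.137. Disease-associated microglial genes (10 of 25 higher, 5 lower; median log2 change 0.16, camera adjusted p = 0.0308; adjusted p = 0.485 with an estimated correlation) included Cd74 (1.73), Ccl6 (1.31) and Lgals3 (1.23), and Cst7, Gpnmb, Ctsl, Csf1 and Fabp5 fell. Lysosome genes rose in 23 of 42 cases and fell in 8, or 24 and 9 adjusted over the list alone (median log2 change 0.32, camera adjusted p = 0.00494; adjusted p = 0.203 with an estimated correlation), with Naglu at 1.03, the acid lipase gene Lipa at -2.10 and Scarb2 at -1.03.

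Cell cycle genes fell without exception in limma. All 43 S-phase and DNA replication genes were lower (median log2 change -1.78, camera adjusted p = 7.11e-18), including Gins1 (-2.58), the ribonucleotide reductase gene Rrm2 (-2.19) and E2f8 (-2.16). All 40 mitotic genes were lower as well (median log2 change -2.08, camera adjusted p = 7.11e-18; adjusted p = 0.111 with an estimated correlation), with Kif2c at -2.58. Replication-dependent histone genes went the other way: 22 of 41 rose and 4 fell (median log2 change 0.56, camera adjusted p = 8.72e-05; 23 and 5 adjusted over the list alone). Hist1h4n rose from 3.89 ± 1.37 to 39.5 ± 8.09 FPKM and Hist1h4h from 2.71 ± 0.326 to 17.8 ± 4.14. Those that fell were Hist1h1c, Hist1h2ah, Hist1h3g and Hist1h3i. Near-identical histone copies can share reads, so values of single histone genes are uncertain. How fully the mRNA kit captures histone transcripts was not tested, so this need not be a rise of all histone RNA. Integrated stress response genes fell in 30 of 44 cases and rose in 7 (median log2 change -0.48, camera adjusted p = 0.000703; adjusted p = 0.324 with an estimated correlation). The amino acid transporter gene Slc7a5 was at -1.93, the serine pathway genes Shmt2 and Phgdh were at -1.83 and -1.37, and Ddit4, also a hypoxia target, was at 1.48.

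The remaining 10 of 26 tested lists were not called in hypoxia against control. They were ethanolamine and choline phospholipid metabolism, cholesterol synthesis, fatty acid synthesis, the unfolded protein response, NRF2 targets, p53 targets, antigen presentation, ribosomal proteins, and the nuclear-encoded and mitochondrially encoded respiratory genes. Members still moved in both directions. Of 36 phospholipid genes 11 rose and 8 fell (camera adjusted p = 0.436), with the lipin genes Lpin1 and Lpin2 at 1.53 and 1.37, Phospho1 at 1.41 and Pld2 at 1.09. Etnk1, which encodes ethanolamine kinase, was 8.09 ± 0.907 FPKM in control and 9.83 ± 0.963 in hypoxia (limma adjusted p = 0.0377), a call kept in 11 of 19 other settings. Pcyt2, the next enzyme of the same pathway, was 15.3 ± 2.46 and 14.9 ± 0.801 FPKM (limma adjusted p = 0.863). The cyclin-dependent kinase inhibitor gene Cdkn1a rose from 14.3 ± 0.592 to 166 ± 12.97 FPKM (log2 change 3.49, SE 0.07, limma adjusted p = 4.47e-09) within a p53 list of 5 higher and 5 lower members. The oxidative stress gene Hmox1 rose from 278 ± 11.3 to 809 ± 60.8 FPKM, and Nqo1 fell from 7.30 ± 0.489 to 1.15 ± 0.104. Ribosomal RNA-like transcripts held 4.69 ± 2.75% of all FPKM in control, 10.1 ± 2.24% in hypoxia and 8.57 ± 2.73% with ethanolamine. Mitochondrial genes held 11.8 ± 0.471%, 10.1 ± 0.595% and 12.04 ± 0.379%. Camera was run with a preset correlation, which called 16 lists. With an estimated correlation 7 held, most of them close to the threshold. Their camera adjusted p was then 0.00857 for S-phase genes, 0.034 for histones, 0.0365 for pro-inflammatory genes and 0.042 for HIF targets. It was 0.0485 for each of autophagy, angiogenic factors and alternative activation. Without a filter on low values the median was 0.14 for homeostatic microglial genes, 0.53 for angiogenic factors, 0.44 for alternative activation and 0.28 for histones. The homeostatic, interferon-stimulated and disease-associated calls were kept in 18, 17 and 15 of 20 other settings.

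**Figure D1:**
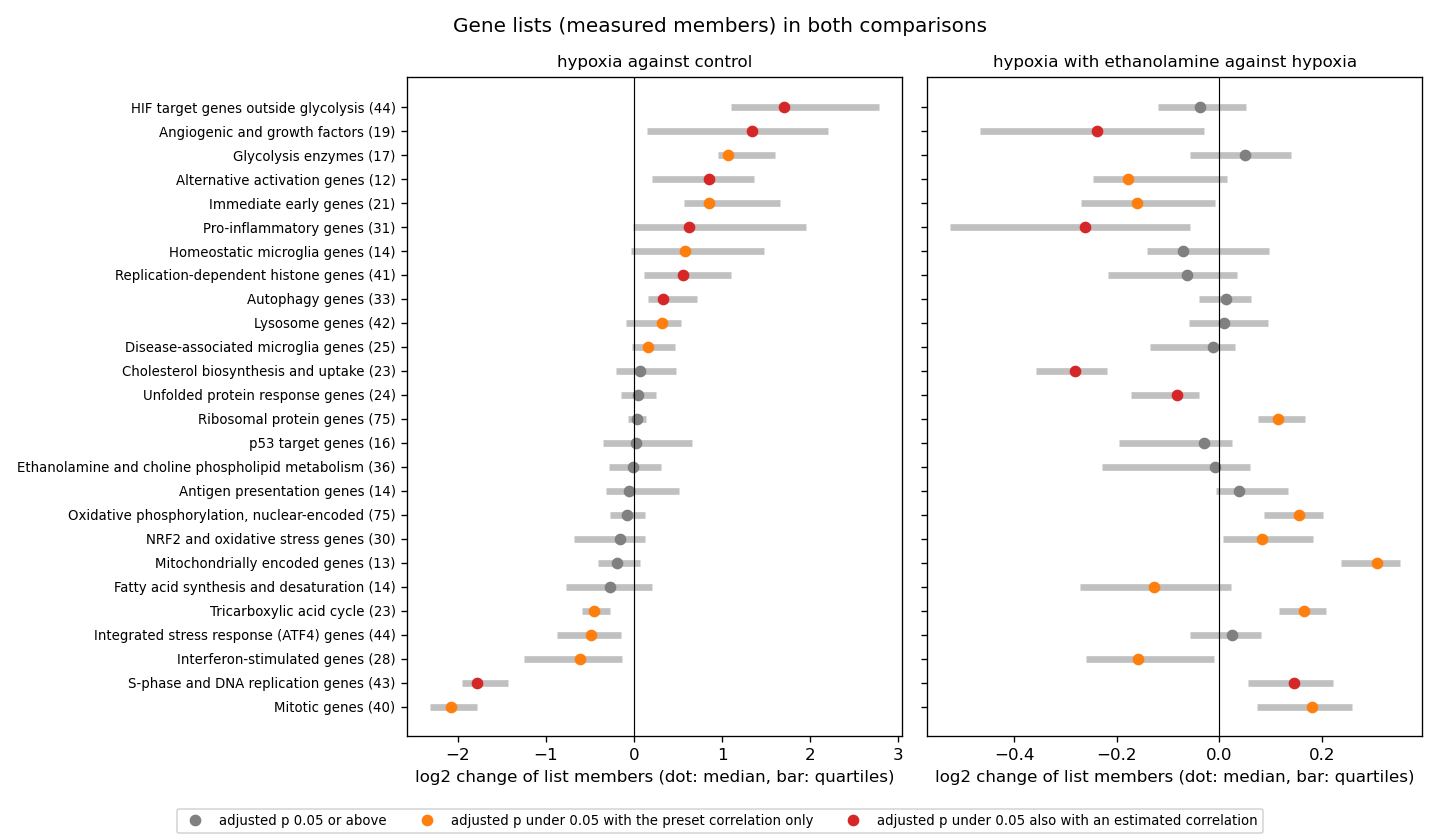
Median log2 change (dot) and quartiles (bar) of the members of 26 gene lists, for hypoxia against control (left) and hypoxia with ethanolamine against hypoxia (right), with the number of measured members in brackets; the x axes differ in range. Mitotic genes lay lowest under hypoxia (-2.08), and cholesterol genes lay lowest with ethanolamine (-0.28).

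The comparison of hypoxia with and without ethanolamine asked what the supplement changes when labelled time and oxygen are equal. Il1b, which encodes a cytokine of the interleukin-1 family, fell from 29.8 ± 5.90 FPKM in hypoxia to 12.1 ± 0.465 with ethanolamine (SD, n = 3; log2 change -1.25, SE 0.13, limma adjusted p = 0.0153). Cxcl2 fell from 93.2 ± 18.5 to 40.7 ± 4.05 FPKM (log2 change -1.17, SE 0.14, limma adjusted p = 0.019), and Ptgs2 from 136 ± 18.6 to 85.4 ± 4.62 (log2 change -0.66, SE 0.10, limma adjusted p = 0.0329). Mmp12 fell from 40.00 ± 7.69 to 20.4 ± 0.624 (log2 change -0.94, SE 0.12, limma adjusted p = 0.0219). Few genes were called, which does not show that few changed. In limma 67 of 11802 genes passed, 14 higher and 53 lower. Of these, 9 of the lower ones and none of the higher ones had an absolute log2 change of at least 1. At an unadjusted p under 0.05 there were 1730 genes. Among genes with a symbol and a mean of at least 5 FPKM, the lowest changes were those of Il1b, the nuclear long non-coding RNA Malat1 (-1.23), Cxcl2, Mir5125 (-1.13), Mmp12 and Prss46 (-0.79). The annotated Mir5125 lies inside Srrm2 on the same strand, so its value is uncertain. The highest at that level were Mnd1 (0.60), Lage3 (0.53), Akr7a5 (0.49), Wdr34 (0.48), Angptl2 (0.47) and Tbc1d5 (0.43), with limma adjusted p of 0.0342 to 0.0471.

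The number of called genes depended on single libraries. Without control library 1, 2 or 3, limma called 38, 32 or 23 genes, and without hypoxia library 1, 2 or 3 it called 23, 3 or 0 (1709 at an unadjusted p under 0.05 in the last case). Without supplemented library 1, 2 or 3 it called 22, 5 or 12. A fit to the 6 libraries of these groups alone called 6 genes, and rescaling without ribosomal and mitochondrial RNA, chosen after seeing the data, called 36, of which 1 was higher and 35 were lower. Among the genes above, calls were kept in 16 of 20 other settings by Il1b, 14 by Cxcl2, 13 by Prss46, 11 by Mmp12, 10 by Mir5125, 9 by Ptgs2, 8 by Lage3, 7 by Tbc1d5, 6 by Mnd1, 5 by Malat1 and Angptl2, 4 by Wdr34 and 3 by Akr7a5, all with the same direction.

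Pro-inflammatory genes were lower with ethanolamine as a list (median log2 change -0.26, camera adjusted p = 4.07e-10). Of 31 measured members 24 had a negative change, 5 passed over all genes (Il1b, Cxcl2, Ptgs2, Cxcl10 and Ccl5) and 14 passed when adjusted over the list alone. Cxcl10, already lower in hypoxia, went from 1.13 ± 0.215 to 0.403 ± 0.0335 FPKM (log2 change -0.84, SE 0.12, limma adjusted p = 0.0271). The chemokine gene Ccl5 went from 11.1 ± 0.652 to 6.78 ± 0.422 FPKM (log2 change -0.68, SE 0.11, limma adjusted p = 0.0399), calls kept in 9 of 19 and 7 of 20 other settings. The changes of Nos2 (-0.35, limma adjusted p = 0.0705), Il6 (-0.73, limma adjusted p = 0.154) and Tnf (-0.22, limma adjusted p = 0.27) did not pass. Angiogenic and growth factor genes were lower as a list (median log2 change -0.24, camera adjusted p = 4.73e-07): Mmp12 alone passed over all genes and 9 of 19 passed adjusted over the list alone. Without a filter on low values its median was -0.11. Vegfa was 34.97 ± 1.90 FPKM in hypoxia and 30.8 ± 2.08 with ethanolamine (limma adjusted p = 0.254).

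Genes of cholesterol synthesis and uptake were lower as a list (median log2 change -0.28, camera adjusted p = 7.68e-13). Of 23 members 22 had a negative change, 2 passed over all genes, among them Idi1, and 13 passed adjusted over the list alone. Idi1, which encodes isopentenyl diphosphate isomerase, fell from 64.7 ± 6.55 to 44.6 ± 3.11 FPKM (log2 change -0.53, SE 0.09, limma adjusted p = 0.0436). The fatty acid synthase gene Fasn fell from 72.7 ± 4.63 to 49.7 ± 5.01 FPKM (log2 change -0.55, SE 0.09, limma adjusted p = 0.0436). These calls were kept in only 5 (Idi1) and 4 (Fasn) of 20 other settings. Fasn belongs to a fatty acid list with median log2 change -0.13, camera adjusted p = 0.00957 and adjusted p = 0.229 with an estimated correlation. Without hypoxia library 2 the median of that list was -0.07, and without supplemented library 3 it was -0.08. Unfolded protein response genes were lower as a list by a small amount (median log2 change -0.08, camera adjusted p = 0.000323), with no member past the threshold in limma and 20 of 24 below 0; its most abundant members Calr (-0.02) and Hsp90b1 (-0.19) had limma adjusted p of 0.883 and 0.198. S-phase genes were higher as a list (median log2 change 0.15, camera adjusted p = 6.06e-08), with 40 of 43 above 0, none passing over all genes and 5 adjusted over the list alone. The cholesterol, unfolded protein response and S-phase lists, with the pro-inflammatory and angiogenic ones, were the 5 of 15 called lists that held with an estimated correlation. Their camera adjusted p was then much larger. It was 0.0124 for pro-inflammatory genes, 0.0371 for cholesterol and for S-phase genes, and 0.0436 for unfolded protein response and for angiogenic genes.

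Respiratory, ribosomal and mitotic genes were slightly higher with ethanolamine, and these calls were lost with an estimated correlation. Hypoxia library 2 had a lower mean log2 level than hypoxia libraries 1 and 3 for ribosomal protein genes (7.56 against 7.82 and 7.84) and oxidative phosphorylation genes (5.33 against 5.52 and 5.58). Without it the medians below fell to 0.03 and 0.08. Supplemented library 1 (7.78) lay below hypoxia libraries 1 and 3 for ribosomal protein genes. For mitotic genes hypoxia library 1 was lower than hypoxia libraries 2 and 3 (2.32 against 2.59 and 2.51), and without it their median was 0.11. Mitochondrially encoded genes had a positive change in all 13 cases (median log2 change 0.31, camera adjusted p = 4.07e-10; adjusted p = 0.124 with an estimated correlation); none passed over all genes and 12 passed adjusted over the list alone. Under quantile normalization the median was 0.14 and mt-Co1 was at -0.16 instead of 0.22. In the same libraries the mitochondrial share of FPKM was 10.1 ± 0.595% without and 12.04 ± 0.379% with the supplement. Nuclear-encoded oxidative phosphorylation genes (72 of 75 positive; median log2 change 0.16, camera adjusted p = 2.81e-09; adjusted p = 0.331 with an estimated correlation) and ribosomal protein genes (72 of 75 positive; median log2 change 0.11, camera adjusted p = 1.74e-06; adjusted p = 0.54 with an estimated correlation) had no single member past the threshold in limma. The same held for tricarboxylic acid cycle genes (median log2 change 0.16, camera adjusted p = 2.34e-07; adjusted p = 0.166 with an estimated correlation), mitotic genes (median log2 change 0.18, camera adjusted p = 1.29e-07; adjusted p = 0.324 with an estimated correlation) and NRF2 targets (median log2 change 0.08, camera adjusted p = 0.034; adjusted p = 0.374 with an estimated correlation). The NRF2 call was kept in only 13 of 21 other settings. Interferon-stimulated genes (median log2 change -0.16, camera adjusted p = 0.0008; adjusted p = 0.374 with an estimated correlation) and immediate early genes (median log2 change -0.16, camera adjusted p = 0.00134; adjusted p = 0.234 with an estimated correlation) were lower. Alternative activation genes were lower (median log2 change -0.18, camera adjusted p = 0.00274; adjusted p = 0.108 with an estimated correlation), and their member Il1rn, the interleukin-1 receptor antagonist gene, fell from 21.6 ± 1.33 to 13.6 ± 0.779 FPKM (limma adjusted p = 0.0219). Without a filter on low values the median was -0.04 for alternative activation and -0.09 for immediate early genes, and with a mean of at least 5 FPKM it was -0.06 for interferon-stimulated genes.

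Hypoxia targets were not called as a list with ethanolamine. The 44 HIF targets had median log2 change -0.04, camera adjusted p = 0.411. Adjusted over the list alone, 2 members were higher (Mt2 and Slc2a3) and 1 was lower (Cxcr4). In 2 of 21 other settings, quantile normalization and a mean of at least 5 FPKM, the list was called lower (lowest camera adjusted p = 0.0426). The 17 glycolysis genes had median log2 change 0.05, camera adjusted p = 0.675. Bnip3 was 298 ± 7.15 FPKM in hypoxia and 303 ± 28.4 with ethanolamine (log2 change 0.02, SE 0.09, limma adjusted p = 0.933). Slc2a1 was 237 ± 16.3 and 229.9 ± 5.05, and Ldha was 566 ± 66.5 and 622 ± 63.99. The phospholipid list had no member past the threshold over all genes in limma (camera adjusted p = 0.182) and 1 higher and 2 lower adjusted over the list alone. These were the choline transporter-like gene Slc44a2 (0.56), Lpcat1 (-0.37) and the choline kinase gene Chka (-0.60), chosen after their values were seen, with limma adjusted p over all genes of 0.0745, 0.0595 and 0.0976. Pcyt2 was 14.9 ± 0.801 FPKM without and 11.8 ± 0.470 with ethanolamine (log2 change -0.32, SE 0.11, limma adjusted p = 0.218). Etnk1 was 9.83 ± 0.963 and 8.05 ± 0.328 FPKM (log2 change -0.27, SE 0.10, limma adjusted p = 0.25). The lists of autophagy, lysosome, integrated stress response, homeostatic and disease-associated microglia, antigen presentation, p53 and histone genes were not called either, although 4 of 21 other settings called the disease-associated and 2 the histone genes, with camera adjusted p of 0.113 to 0.909. In simulated data with the spread of all 9 libraries, 59.7% of genes changed by 0.5 and 94.0% of genes changed by 1 on the log2 scale were recovered for this comparison. With the same spread, 40.3% and 52.2% of genes changed by 0.5 were recovered for the other comparisons, so 59.7% is not particular to this one. The noise was drawn independently per gene, which real libraries need not follow. With a library left out, 0 to 38 real genes were called, so the real power may be lower.

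**Figure D2:**
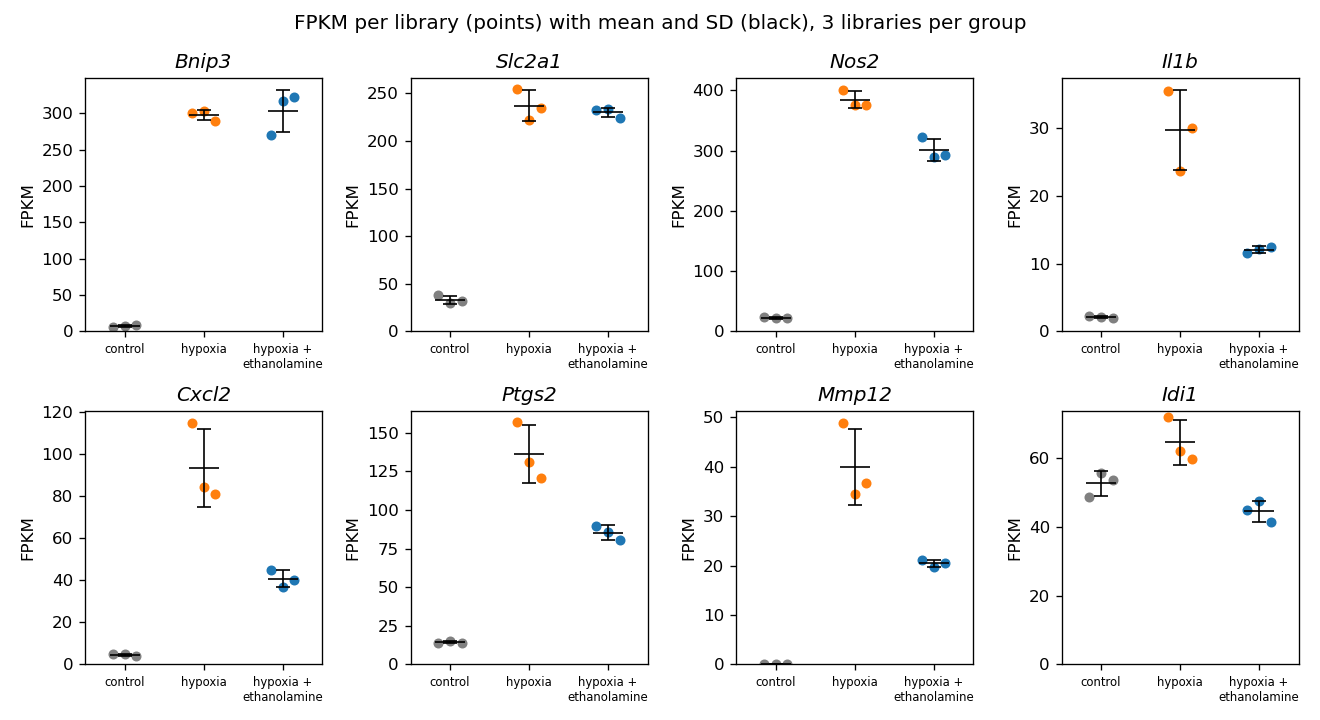
FPKM of 8 genes in each library (points) by group, with group mean and SD in black (n = 3); each y axis starts at 0. Il1b, Cxcl2, Ptgs2 and Mmp12 were lower with ethanolamine than in hypoxia, whereas Bnip3 and Slc2a1 averaged 303 and 229.9 FPKM with the supplement.

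Hypoxic cells with ethanolamine were also compared with control, which shows their state relative to the starting cells. Il1b was 2.15 ± 0.139 FPKM in control and 12.1 ± 0.465 in supplemented cells (SD, n = 3; log2 change 2.25, SE 0.13, limma adjusted p = 9.63e-07), so it was lower than in hypoxia alone and still above control. Cxcl2 (log2 change 3.01, SE 0.14, limma adjusted p = 3.64e-07), Mmp12 (log2 change 5.11, SE 0.12, limma adjusted p = 1.81e-08) and Nos2 (log2 change 3.69, SE 0.07, limma adjusted p = 6.03e-09) were likewise above control, whereas Malat1 (log2 change 0.14, SE 0.20, limma adjusted p = 0.555) and Il6 (log2 change -0.04, SE 0.20, limma adjusted p = 0.873) did not differ detectably from it. Fasn (log2 change -0.61, SE 0.09, limma adjusted p = 0.000439) was below control. In limma 6905 of 11802 genes passed, 2840 higher and 4065 lower, and 1603 had an absolute log2 change of at least 1 (746 higher and 857 lower). HIF targets were higher in 35 of 44 cases (median log2 change 1.58, camera adjusted p = 7.41e-17), glycolysis genes in all 17 (median log2 change 1.16, camera adjusted p = 3.97e-10; adjusted p = 0.137 with an estimated correlation) and pro-inflammatory genes in 17 of 31 (median log2 change 0.37, camera adjusted p = 0.0016; adjusted p = 0.0579 with an estimated correlation). All 43 S-phase genes (median log2 change -1.63, camera adjusted p = 6.21e-18) and all 40 mitotic genes (median log2 change -1.97, camera adjusted p = 6.21e-18; adjusted p = 0.121 with an estimated correlation) were lower. Ribosomal protein genes were higher in 17 of 75 cases (median log2 change 0.16, camera adjusted p = 0.00119; adjusted p = 0.624 with an estimated correlation), with a median of -0.0219 under quantile normalization. Camera called 17 lists, 12 higher and 5 lower, and 3 held with an estimated correlation. These were S-phase genes (camera adjusted p = 0.00872), histones (0.037) and HIF targets (0.0492).

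Genes called in both hypoxia against control and ethanolamine against hypoxia were counted by sign, to see whether the supplement moved hypoxia-changed genes back. Of 59 such genes, 42 were higher in hypoxia and lower with ethanolamine, and 10 were lower in hypoxia and higher with ethanolamine. Another 7 were lower in both and none was higher in both. Independent lists of these sizes would give 17.96 genes of opposite and 21.84 of the same sign. The opposite-sign genes with the largest changes in both were Usf3, Il1b, Malat1, the unnamed gene ENSMUSG00000115840, Cxcl2 and the stromelysin gene Mmp10. Usf3, a transcription factor gene, was 1.14 ± 0.611 FPKM in control, 5.09 ± 0.329 in hypoxia and 0.411 ± 0.315 with ethanolamine. Those lower in both were led by Cxcl10, Mir5125, Rhou and Zfp692. The hypoxia libraries enter both comparisons with opposite signs, which can give opposite signs without any effect of ethanolamine. In 100 simulated data sets without any ethanolamine effect, 0.400 opposite-sign genes were called on average and at most 31, and none were called when all groups were unchanged. An earlier version of the simulation, replaced after its result was seen, drew residuals with replacement and gave 12.8 on average, at most 638, with 2 of 100 draws at 52 or more. The covariance of both log2 changes across genes was -0.07, against -0.02 in the simulation.

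The 3 hypoxia libraries are too few to be divided, so part of the excess may come from sharing them. The count of 52 was 31, 26 or 22 without control library 1, 2 or 3, 21, 3 or 0 without hypoxia library 1, 2 or 3, and 19, 3 or 9 without supplemented library 1, 2 or 3. Raised pro-inflammatory genes (20 genes) gave back 25.7% of their mean hypoxic rise on the log2 scale with ethanolamine, between 20.8% and 29.4% over the 9 pairs of a hypoxia and a supplemented library. Raised HIF targets (36 genes) gave back 0.845%, between -3.04% and 6.36%, and raised glycolysis genes (17 genes) -2.92%, between -16.7% and 3.46%.

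**Figure D3:**
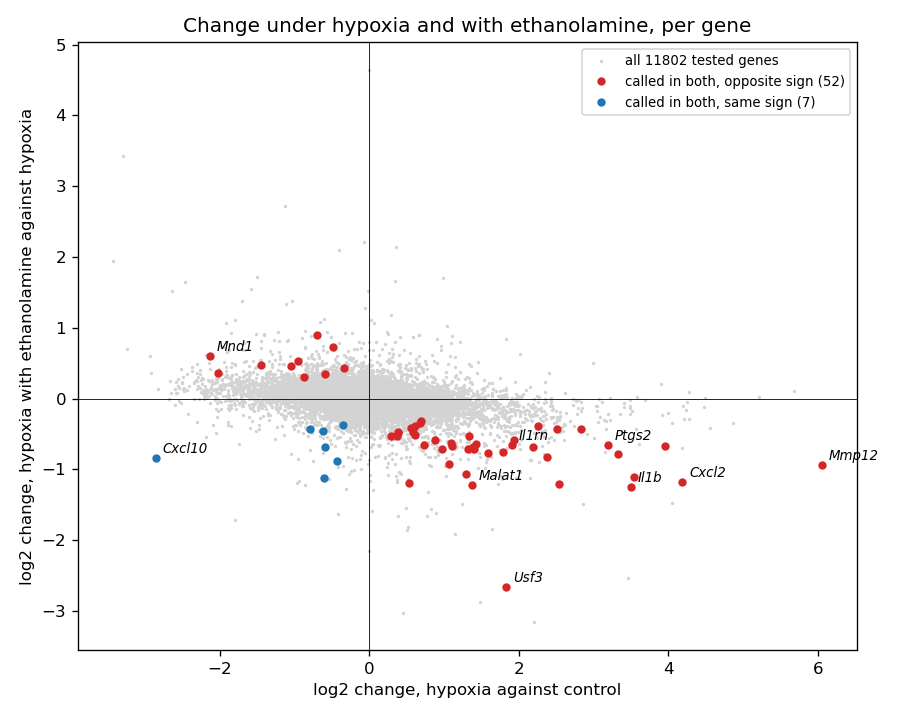
Log2 change in hypoxia against control (x axis) and in hypoxia with ethanolamine against hypoxia (y axis) for 11802 genes (gray), with the 52 genes called in both with opposite signs in red and the 7 with the same sign in blue. Il1b lay at 3.50 and -1.25, and Cxcl10 at -2.85 and -0.84.

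Few markers of other cell types reached a mean of 1 FPKM. Among adipocyte markers 3 of 12 did: Fabp4 (21.5 FPKM), a gene that macrophages also express, Pnpla2 (16.2 FPKM) and Lipe (1.49 FPKM). Glul (33.2 FPKM) was the only astrocyte or Müller glia marker of 10 at that level. Syn1 (7.69 FPKM) was the only neuronal marker of 13 and Cnp (6.51 FPKM) the only oligodendrocyte marker of 10. Vwf (2.15 FPKM) and Egfl7 were the only endothelial markers of 10, and none of 10 fibroblast markers reached it. Vwf rose in hypoxia (log2 change 1.10, SE 0.09, limma adjusted p = 6.1e-06) and fell with ethanolamine (log2 change -0.67, SE 0.09, limma adjusted p = 0.0219), whereas Egfl7, which overlaps Agpat2, fell in hypoxia (log2 change -0.41, SE 0.12, limma adjusted p = 0.0135) and was at 0.49 with ethanolamine (limma adjusted p = 0.115). Fabp4 (log2 change 0.47, SE 0.10, limma adjusted p = 0.00344) also rose in hypoxia, as did Syn1 (log2 change 0.46, SE 0.06, limma adjusted p = 0.000185), which overlaps Araf, Timp1 and Gm15029 on the opposite strand. These marker genes were chosen after their values were seen. Il1b (ENSMUSG00000027398, GRCm38 chromosome 2, 129364570 to 129371139, minus strand) overlaps the antisense gene Il1bos. Mmp12 (ENSMUSG00000049723, GRCm38 chromosome 9, 7344381 to 7369499, plus strand) overlaps Mmp1b on the opposite strand. The sources used here do not give whether counting used strand, so reads of these partners cannot be told apart. Cxcl2 (ENSMUSG00000058427, GRCm38 chromosome 5, 90903871 to 90905938, plus strand) and Ptgs2 (ENSMUSG00000032487, GRCm38 chromosome 1, 150100031 to 150108227, plus strand) overlap no other annotated gene.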

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

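The length and GC correction and the rescaling without ribosomal and mitochondrial RNA were chosen only after the data were seen; the other settings were planned. Between ethanolamine and hypoxia, the 67 called genes became 40 without a filter, 6 with only the libraries of these groups (fewer samples for the spread), 9 at a log2 change of at least 1, 36 after the rescaling and 128 after the length and GC correction. Leaving out each library gave 0 to 38. The 52 genes moved back became 34 without a filter and 30 after the rescaling, and 0 to 31 with a library left out; this count has no value for the fit to only 2 groups. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.117 to 0.109, those of other pairs at -0.163 to 0.163, and 2 of 9 libraries correlated best with their own number. With the number as a block, limma called 0 genes between ethanolamine and hypoxia (1629 at an unadjusted p under 0.05) and moved 0 back, while the count for hypoxia against control was 6901. For hypoxia against control 4671 genes were called with a mean of at least 5 FPKM, where fewer genes are tested, and 1808 at a log2 change of at least 1; for ethanolamine against control the counts were 4603 and 1603. With an estimated correlation the called lists went from 16 to 7, from 15 to 5 and from 17 to 3. Quantile normalization turned ribosomal protein genes to a median of -0.0219 and mt-Co1 to -0.71 for ethanolamine against control. Where other counts changed, the cause was not tested. Other totals of called genes, called lists and genes moved back stayed within 1.5 times the reported one. The 14 higher genes with ethanolamine became 7 without the mean-variance trend, 5 without a filter, 0 to 4 with a library left out and 28 after the length and GC correction, and the 1730 genes at an unadjusted p under 0.05 became 3038 without a filter. Each pair of groups allows 10 splits of its 6 libraries, too few for a share under 0.05. Mixed splits also keep part of the group difference and put the rest into the spread. Their counts therefore do not show what an absence of any difference would give, and no conclusion is drawn from them. Genes called in the real and the highest other split were 7011 and 1 (hypoxia against control), 67 and 4 (ethanolamine against hypoxia) and 6905 and 2 (ethanolamine against control); lists called were 16 and 17, 15 and 10, and 17 and 18, with 4, 1 and 2 splits as large; genes moved back were 52 and 4. The unknown absolute depth leaves the counting error of low values unknown.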

Other observations

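The tests of shared libraries, weaker hypoxia and nuclear RNA, and the genes of this and the next paragraph, were chosen only after the result was seen. A compact group of stefin A-like protease inhibitor genes on chromosome 16 (GRCm38) rose together in hypoxia: Gm5483 (36184212 to 36188111) from 0.542 ± 0.172 to 29.7 ± 1.71 FPKM, Gm5416 (36210403 to 36217788) from 0.298 ± 0.285 to 14.4 ± 2.81, and 2010005H15Rik (36221468 to 36257444) from 4.17 ± 0.290 to 86.8 ± 17.9, with log2 changes of 4.87, 4.27 and 4.21 (limma adjusted p = 1.33e-08, 1.61e-06 and 4.7e-08). These are close copies of each other, so reads can be shared between them. Selenbp2, a close paralog of Selenbp1, rose from 0.465 ± 0.0982 to 12.1 ± 2.33 FPKM (log2 change 3.69, SE 0.14, limma adjusted p = 9.73e-08), with the same caution.

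Several genes used to recognise microglia were low in these BV2 libraries. Of 27 homeostatic markers 14 reached a mean of 1 FPKM. Sall1, Siglech, C1qa and C1qb were listed at 0 in all 9 libraries, and P2ry12, Tmem119 and Aif1, which encodes IBA1, averaged 0.0446, 0.464 and 0.103 FPKM over them. The macrophage genes Cd68 (678 FPKM), Tyrobp (112 FPKM) and Trem2 (21.4 FPKM) were higher than these.

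Genes raised by hypoxia and lower with ethanolamine form a pattern that may reflect the supplement, since 42 genes had these signs and a further 10 the reverse. Weaker hypoxia in the supplemented cultures is argued against only as far as HIF targets report it. Raised HIF targets gave back 0.845% of their rise and raised pro-inflammatory genes 25.7%, with the smaller share in 9 of 9 library pairs. These pairs combine only 3 hypoxia and 3 supplemented libraries and are not independent. The fall of the pro-inflammatory genes was known when this comparison was chosen. HIF targets already at a ceiling would not show mildly weaker hypoxia, which was not tested. Sharing the hypoxia libraries cannot be told apart from an effect: the highest of 100 simulated counts was 31 when residuals were shuffled without replacement, but an earlier version that drew them with replacement, replaced after its result was seen because it could repeat a library within a group, reached 638, and 2 of its 100 draws were at least 52. Rescaling without ribosomal and mitochondrial RNA, with a transcript list corrected after a first value was seen, left 29 of 52 genes called. This met the bound of 26, written before that test but after the data were seen. By an interval added afterwards, the count alone was too close to that bound to decide. The median change toward control of the 52 genes was 0.68 after the rescaling and 0.65 before (median SE 0.10 and 0.09). In the 23 genes that lost the call the change was 0.51 (0.53 before) and the SE 0.10 (0.08 before). The rescaling moves all genes of a library by nearly the same amount. It therefore takes the 42 genes and the 10 of reverse sign in opposite ways relative to control. Only such a common shift was tested, not effects on single genes that go with RNA composition. The median log2 change of all tested genes went from 0.013 to -0.018. A shift of that size is small beside 0.65, which argues against a common scaling by that RNA share for the 52 genes as a set. All called genes higher with ethanolamine went from 14 to 1, so this does not extend to the 10 genes of the reverse sign taken alone.

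Ribosomal protein and respiratory genes were slightly higher with ethanolamine, a call lost with an estimated correlation (adjusted p = 0.54 and 0.331 in limma's camera), with a size that depended on hypoxia library 2, without which the median of their 150 genes was 0.05 instead of 0.14. After a trend on transcript length and GC was removed the median was 0.10 (0.04 without hypoxia library 2), and at the preset correlation camera still called ribosomal proteins, nuclear-encoded and mitochondrially encoded respiratory genes (adjusted p = 0.000394, 6.33e-07 and 1.57e-11), calls that an estimated correlation had already ended before the correction. The corrected median of 0.0955 lay above the bound of 0.0693 written before that test. Less a standard error between libraries of 0.0643, a step added after the result was seen, it was 0.0312 and below the bound. Length and GC therefore cannot be told apart from other causes. Across genes the log2 change correlated with length at a Spearman rho of -0.194. A lower share of nuclear RNA in the supplemented libraries is a candidate explanation. It was examined with long non-coding RNAs taken as nuclear, whose location in these cells was not measured, so Gas5 or others may not report nuclear RNA. Of 5 such RNAs measured besides Malat1, 4 were below 0. Their median was -0.46, at percentile 0.01 of 10000 random lists matched on mean expression. Those lists drew genes independently, whereas RNAs that vary together between libraries can reach such a percentile more often. Nor were they matched on spread. Neat1 and Airn had SEs of 0.24 and 0.32, against a median SE of 0.11 over tested genes, while Firre, Tug1 and Gas5 had 0.10, 0.10 and 0.06. The percentile is therefore no measure of how unusual the fall is. Malat1 was left out only after a first result, and 4 of 5 just meets the bound of 80%. None of the 5 passed in limma: Neat1 was at -1.18 (adjusted p = 0.0795), Airn at -1.02 (0.199), Firre at -0.46 (0.0921), Tug1 at -0.10 (0.675) and Gas5 at 0.08 (0.582), and an effect of ethanolamine on the ribosomal and respiratory genes stays open and untested.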
